A study of Drosophila melanogaster with 4 samples.

How the data were processed

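Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos collected over 0 to 12 h of development, with the polyclonal rabbit antibody RF12 raised against the C-terminal part of the transcription factor Paired (Prd). The series holds 2 groups of 2 samples each, the Prd ChIP libraries and the input DNA libraries, numbered as replicates 1 and 2 in their titles. The strain carries the markers y, cn, bw and sp, the same markers as the strain from which the reference genome was sequenced.

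The deposited data analysed here are 1 list of 1348 peaks for the whole series. Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 were used and the genome build was BDGP5. Per the file headers, the list is in GFF version 3 on FlyBase release 5, and its source field names MACS. Whether the ChIP libraries were pooled for peak calling, which thresholds were applied, and how reads mapping to several places were treated are not given in the sources used here. Each peak has a first and last base and 1 score, which the authors deposited without naming the quantity. The list has no value per library, so no replicate spread, no library depth and no comparison between replicates could be computed. All intervals and p-values below treat peaks as independent counts and cover counting error only. They say nothing about the reproducibility of a peak between embryo collections, and peaks are not biological replicates.

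The scores were examined to find out what they hold. If a score is minus log10 of a Poisson upper-tail probability against 1 genome-wide background, the scores can take only the values given by whole numbers of reads k, that is −log10 P(X ≥ k). The Poisson mean was fitted by maximising the share of scores within 0.01 of such a value, over means from 20 to 150 in steps of 0.01 and then more finely. The best mean was 56.19 reads, at which 835 of the 1348 scores, or 61.9%, lay within 0.01 of a ladder value. Lists in which every score was moved at random within its ladder step, with the mean fitted again, reached 10.7% on average and 11.6% at most over 100 draws. Scores within 0.01 are called ladder scores, the others off-ladder scores, and for ladder scores k and the fold k over 56.19 are given. With the convention P(X > k) every k is lower by 1 read.

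Sequence names were kept as in the list. The chromosome arms 2L, 2R, 3L, 3R, X and 4 are called the 6 arms. The 6 sequences with names ending in Het hold heterochromatin assigned to a chromosome, and U and Uextra hold scaffolds that release 5 did not place, joined in no genomic order. A genome and an annotation of release 5 were not used here, and the gene table at hand is on release 6. Coordinates were not converted, so peaks are given by position without gene names, and the planned analyses of annotation classes, gene lists and sequence motifs were not run. The highest peak end on a sequence stood for its length, so each density in peaks per Mb is an upper estimate.

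The rule for named peaks and the tests of close neighbours and of score with width were fixed before the data were examined. The test of X was planned for known arm lengths, and without them only counts and highest peak ends were to be given, so running it was chosen after the list had been seen. The named peaks are the 25 with the highest score and the 5 runs with the most peaks, a run being peaks whose neighbours lie under 10 kb apart, middle to middle. The share of X among peaks on the 5 large arms was compared with the share of length in a two-sided exact binomial test. Close neighbours were counted and compared with 10000 random placements of the same number of peaks between the first and last peak of each sequence, one-sided for more, as a permutation test of positions. Score and width were related across peaks by Spearman and Pearson coefficients with two-sided permutation p-values from 100000 draws. The 3 p-values were adjusted by the Benjamini-Hochberg method. The ladder, the comparison of the 6 arms with the other sequences, and the restriction of clustering to the 6 arms were chosen after the list had been seen. Medians were compared by permutation of the sequence class over 100000 draws, with 95% bootstrap intervals from 2000 draws. Intervals of shares are exact Clopper-Pearson and those of densities exact Poisson, at 95%.

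Other settings fixed beforehand were the upper 50% of the peaks by score, merging of peaks under 1 kb apart, spacings of 5 kb and 50 kb, and leaving out the 2 peaks of the most extreme width. Both methods were tested on simulated data of the same 1348 peaks. Random placement called 2% of 100 unclustered lists past 0.05 and 94% of 100 lists with 40 planted close neighbours. The ladder fit, on 1 simulated list, recovered a mean of 40.25 and the k of 100% of the simulated ladder scores that it found. It placed 62.6% of the scores on the ladder where 60.8% were simulated on it. Scores that land on the ladder by chance were left out of that 100%, and their k has no meaning. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.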

Results

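Binding of Prd, a transcription factor with a paired domain and a homeodomain that acts in the segmentation of the Drosophila embryo, was profiled by ChIP-seq in embryos of 0 to 12 h. The design sets 2 libraries precipitated with the anti-Prd antibody RF12 against 2 input DNA libraries from the same strain and stage, and the comparison asks where in the genome Prd antibody signal exceeds input. The answer is given by 1 list of 1348 peaks, called by the authors for the series as a whole. The number of reads per library is unknown, and with no value per library the spread between replicates could not be measured.

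The peaks with the highest scores lay on the assembled chromosome arms. All 25 highest peaks were on the 6 arms, 8 of them on 2R, 5 on 2L, 4 each on 3L and 3R, 3 on X and 1 on chromosome 4. The peaks covered 482 kb in all. Their median width was 306 bp, with quartiles of 243 and 411 bp and a maximum of 1933 bp, and 50 peaks shared the smallest width. Scores ran from 6.2 to 166.55 with a median of 14.4, and only 14 peaks scored above 100, all of them on the 5 large arms.

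The highest peak was on 2R from 21070286 to 21070992, with a score of 166.55. A second high-scoring peak lay 7132 bp away on the same arm, from 21077016 to 21078526, with a score of 123.49 and a width of 1511 bp. No other 2 of the 25 highest peaks were nearest neighbours within 10 kb. The next regions by score were 2L 12520197 to 12520749 with a score of 138.69, 3R 796220 to 797126 with 136.38, 3L 505710 to 506369 with 133.32, and 3R 12086145 to 12086917 with 132.55. They were followed by 2L 8888679 to 8889230 at 118.3 and 3L 14104523 to 14104979 at 110.28. On X the highest peaks were 17645605 to 17646094 with 106.69, 17425953 to 17426573 with 105.98 and 423827 to 424354 with 102.43. Scores above 100 were also held by 3R 6500866 to 6501543 with 104.56, 2R 4138945 to 4139411 with 103.14 and 3L 9039995 to 9040606 with 100.33.

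The remaining 11 of the 25 highest peaks scored between 80.04 and 94.77. On 2L these began at 14588855, 3657335 and 9612580, and on 2R at 3073955, 12687565, 1580595, 16825605 and 2038531. The others were at 26737892 on 3R, at 14205355 on 3L and at 855691 on chromosome 4, the last with a width of 1113 bp.

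**Figure D1:**
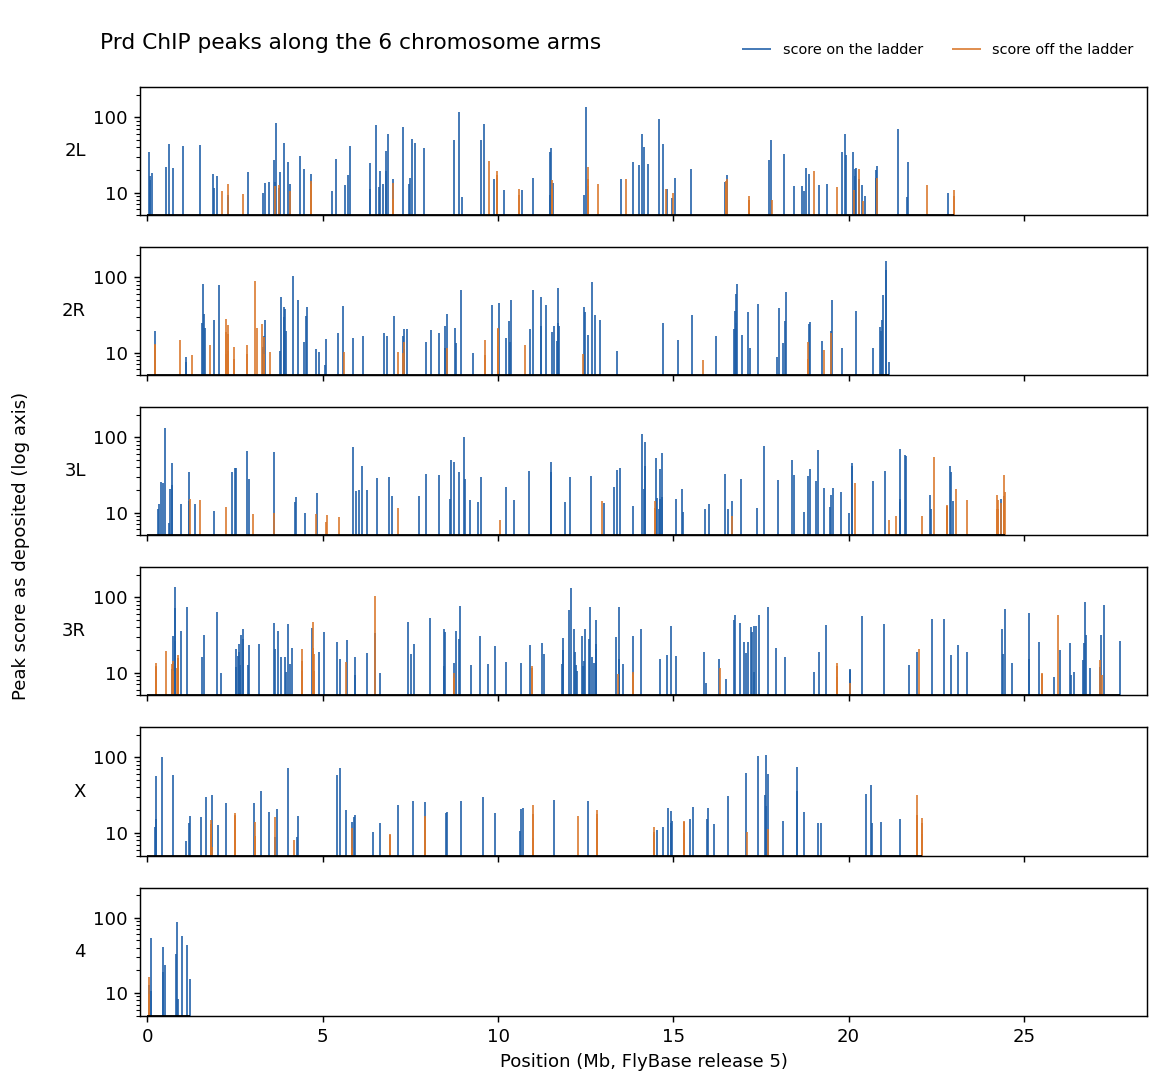
Positions of the 777 peaks on the 6 arms (horizontal axis, Mb on FlyBase release 5), each drawn as a vertical line up to its deposited score (log axis), blue for ladder scores and orange for off-ladder scores, with the black baseline ending at the highest peak end of the arm. The highest lines stand at 21.07 Mb on 2R, 12.52 Mb on 2L and 0.80 Mb on 3R.

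Most scores matched minus log10 of a Poisson upper-tail probability with a common mean of 56.19 reads, within 0.01. This held for 835 of the 1348 peaks, against 10.7% on average when the scores were moved at random within a step and the mean was fitted again, and for 95 of the 100 highest peaks. For these ladder scores a number of reads at the peak, k, could be inferred. It is the k of the nearest ladder value under the fitted mean, not an observed count. Scores on the ladder by chance carry no true k. The inferred k ran from 99 to 368 reads, which is 1.76 to 6.55 times the common mean. The highest peak, on 2R, had a k of 368 and the second highest, on 2L, a k of 333. The median k was 142 reads or 2.53-fold for the 560 ladder peaks on the 6 arms, and 116 reads or 2.06-fold for the 275 on other sequences.

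Peaks were spread over all 6 arms, with the highest density among the large arms on 3R and the lowest on X. The arm 3R had 202 peaks or 7.28 per Mb (95% interval 6.31 to 8.35), 2R had 146 or 6.91 per Mb (5.83 to 8.12), and 2L had 153 or 6.65 per Mb (5.64 to 7.79). On 3L there were 145 peaks or 5.93 per Mb (5.00 to 6.98). X had 117 peaks or 5.29 per Mb (4.38 to 6.34), and chromosome 4 had 14 or 11.4 per Mb (6.25 to 19.2). X held 15.3% of the peaks on the 5 large arms (95% interval 12.9% to 18.1%) and 18.7% of their length, a deficit in an exact binomial test (p = 0.0177, also after adjustment over 3 tests) that was run with highest peak ends as lengths only after the list had been seen. Among ladder peaks the share of X was 13.0% (10.3% to 16.1%, exact p = 0.000435), but ladder scores were themselves less frequent on X, at 60.7% of its peaks against 69.9% to 76.2% on 2L, 2R, 3L and 3R. Median scores were 21.0 on chromosome 4, 19.2 on 2R, 18.4 on 3R, 18.0 on 3L, 16.1 on X and 15.4 on 2L.

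Heterochromatic and unplaced sequences carried 571 of the 1348 peaks, or 42.4% (95% interval 39.7% to 45.0%), but few of those with high scores. Of these, 372 were on Uextra, 100 on U, and 99 on the Het sequences, of which 3RHet had 42, 3LHet 28 and 2RHet 19. By highest peak ends these sequences made up 27.8% of the length, and the share of peaks was higher than that in an exact binomial test (p = 3.63e-30). Their median score was 12.1 against 17.3 on the 6 arms, a difference of 5.13 (95% interval 4.09 to 6.33, permutation p = 1e-05, the smallest that 100000 draws can give). Among ladder peaks the medians were 11.7 and 21.2, a difference of 9.48 (8.35 to 11.9). Their peaks were also narrower, with a median of 281 bp against 324 bp (difference 43 bp, 27 to 62 bp, permutation p = 1e-05). In the upper 50% of the list by score their share was 28.3%, which the exact binomial test did not separate from the share of length (p = 0.764). In the highest 10% it was 1.48%, or 2 of 135 peaks. Their highest peak was on 2RHet from 369912 to 370614, with a score of 72.98.

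**Figure D2:**
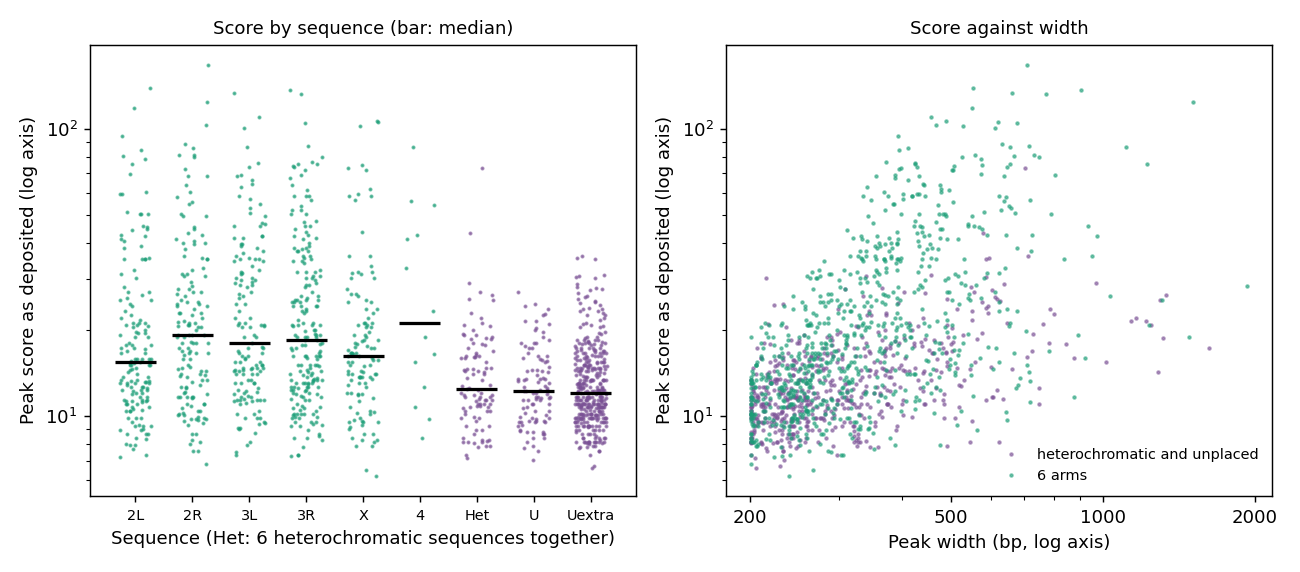
Left, the score of each peak (points, log axis) on each of the 6 arms, on the 6 Het sequences together, and on U and Uextra, with bars at the medians. Right, score against width (both log axes) for peaks on the 6 arms (green) and on heterochromatic and unplaced sequences (purple). Medians lie between 15.4 and 21.0 on the 6 arms and between 12.0 and 12.4 on the other 3 sets, and scores rise with width.

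Peaks lay closer together than random placement would put them. Over the whole list 355 pairs of neighbours were under 10 kb apart, against 120 ± 10.0 (mean ± SD) in random placements, a ratio of 2.95 (one-sided permutation p by random placement = 1e-04, the smallest that 10000 placements can give; adjusted p = 0.00015). The ratio was 1.94 after merging peaks under 1 kb apart, 4.62 at a spacing of 5 kb and 1.33 at 50 kb. Neighbours on U and Uextra need not be neighbours in the genome. On the 6 arms alone there were 168 such pairs against 49.7 ± 6.65, a ratio of 3.38 (permutation p = 1e-04). Merging peaks under 1 kb apart lowered this to 78 pairs against 39.1 ± 5.86, a ratio of 1.99, and placement inside 200 kb windows gave a ratio of 2.10 (both permutation p = 1e-04). Without merging, 261 of the 777 peaks, or 33.6%, stood in 93 runs of 2 or more. For ladder peaks of the 6 arms the ratio was 1.60, from 43 pairs against 26.8 ± 4.89 (permutation p = 0.0014).

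Peaks with a close neighbour scored lower than peaks without one. On the 6 arms their median score was 13.7 against 20.8 for the 516 peaks standing alone (difference -7.08, 95% interval -8.48 to -5.18, permutation p = 1e-05). Ladder scores were held by 38.7% of the peaks in runs and by 89.0% of those alone. Off-ladder scores do not match the common mean, so the lower median score need not mean fewer reads. The 5 runs with the most peaks were on U from 3393215 to 3409560 with 15 peaks, on Uextra from 76987 to 123846 with 14, on 3R from 4724934 to 4738470 with 11, on 2RHet from 2082666 to 2093970 with 8, and on 3LHet from 2203750 to 2208531 with 6. A further 2 runs on 3RHet and 1 on 3R also had 6 peaks and a lower maximum. The run on 3R spanned 13.5 kb, with scores from 7.32 to 47.38.

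Wider peaks had higher scores. Across the 1348 peaks the Spearman coefficient of score with width was 0.57 and the Pearson coefficient 0.43 (both permutation p = 1e-05, the Spearman p adjusted to 3e-05). Without the 2 peaks of the most extreme width the coefficients were 0.57 and 0.45. The Spearman coefficient was 0.61 on the 6 arms and 0.48 on heterochromatic and unplaced sequences. Score and width are taken from the same call, so this relation describes the list and is no evidence about binding.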

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

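Of 23 alternatives run, 21 kept the direction of their result and its side of 0.05. The exceptions concern the share of peaks on heterochromatic and unplaced sequences, which was 42.4% in the whole list. It was 28.3% in the upper 50% by score, not separated from the 27.8% of length (exact binomial p = 0.764), and 1.48% in the highest 10%, below the share of length. The drop follows from the lower scores of these peaks. The share was 41.2% after merging peaks under 1 kb apart and 32.9% among ladder peaks. The ratio of close neighbours to random placement moved from 2.95 to 4.62 at a spacing of 5 kb, 1.33 at 50 kb and 1.94 after merging, each past the threshold. On the 6 arms alone it was 3.38, and 1.99 after merging, 2.10 with placement inside 200 kb windows and 1.60 for ladder peaks, again past it. The difference in median score between the 6 arms and the other sequences moved from 5.13 to 9.48 for ladder peaks. The share of X stayed between 13.0% and 15.3%, and the Spearman coefficient of score with width between 0.43 and 0.64. The binomial test of X itself and settings that use the ladder, the highest 10% or the 6 arms alone, and all of those for the share of peaks off the arms, were chosen after seeing the data. No paired analysis was possible because the peak list has no values per library, so replicates could not be left out in turn either. The planned analyses of annotation classes, gene lists and motifs, with their alternatives, were not run. Depth is unknown, and every result is limited to peaks above the authors' threshold. Any signal below that threshold is absent from this list. The lowest inferred k among ladder peaks was 99 reads, or 1.76-fold. Off-ladder peaks have no inferred k, so this value is not the authors' threshold.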

Other observations

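Further regions stood out by the density or the make-up of their peaks. The first 1000000 bp of 3R held 25 peaks, the most of any 1 Mb bin on the 6 arms, with a median score of 13.9 and ladder scores at 36% of them. Runs of 6, 5, 5 and 5 peaks lay in this bin. The bin of 3R from 4000001 to 5000000 followed with 19 peaks, a median score of 14.4 and ladder scores at 42.1%. It included a run of 11 peaks and a run of 3. The bin of 3R from 12000001 to 13000000 held 17 peaks, with a median score of 24.1, and all of these had ladder scores, as did the 13 peaks of the bin of 3R from 2000001 to 3000000. A run of 5 peaks, all with ladder scores, lay on 3R from 788483 to 799190, with a median score of 26.3, and included the third highest peak of the list. Of the 39 runs of 3 or more peaks on the 6 arms, 3 had ladder scores throughout, and the others of these 3 were on 3L from 21469827 to 21477383 and on 2L from 20183323 to 20197450.

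The 2 Mb beside the centromere held 14.5 peaks per Mb on 3R against 6.72 on the rest of the arm (ratio 2.16, exact binomial p = 0.000524, adjusted over 5 arms p = 0.00262). On 3L the densities were 10.5 and 5.52 per Mb (ratio 1.90, adjusted exact p = 0.0235). The ratios were 1.26 on X, 0.94 on 2R and 0.50 on 2L, with adjusted exact p-values of 0.524, 1 and 0.138. Ladder scores were held by 44.8% of the peaks in the window of 3R, against 81.5% on the rest of that arm. On 3L the shares were 28.6% and 83.9%. The window of 3R held runs of 6, 5, 5 and 5 peaks, and that of 3L runs of 5 and 4. Each peak of a run counts as independent in these tests, so they cannot tell a dense region from a few runs. Merged peaks were not counted for these windows. Chromosome 4, which is largely heterochromatic, held 1.80% of the peaks on the 6 arms (95% interval 0.99% to 3.00%) and 1.02% of their length (exact binomial p = 0.0459, not adjusted), a borderline value, since the interval holds the share of length. On chromosome 4, 85.7% of the 14 peaks had ladder scores and the median score was 21.0, so its peaks did not share the low scores of the Het sequences. These regions and tests were chosen after seeing the data.

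In the 3 patterns weighed below, the tests of weak calls and of pileup heights on X were chosen only after their results had been seen, and those of raised local background, in both patterns, and of the dose of X only after closely related values had been seen. That a ratio must pass its bound by more than its spread was required only after the ratios had been seen. The design offers no group that bears on a biological explanation, so none was tested, and binding of Prd itself stays open throughout.

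The first pattern is the large share of peaks on heterochromatic and unplaced sequences. If repeated sequence raised the local background there, MACS would test those peaks against a local mean above the common one and their scores would leave the ladder. Within 10 bands of like score, off-ladder scores were more frequent there than on the 6 arms by 14.1 percentage points (95% interval 8.52 to 19.7, permutation p = 1e-04, the smallest possible), which is consistent with a raised local background at part of these peaks. Without matching for score, ladder shares were 32.1% on 3LHet, 36% on U, 47.4% on 2RHet, 50.8% on Uextra and 69.0% on 3RHet. On the 6 arms the share was 72.1%. Among ladder peaks alone, 32.9% (29.8% to 36.2%) still lay on these sequences against 27.8% of the length (exact binomial p = 0.00117). A local mean above the common one gives a lower score at the same number of reads. Off-ladder scores thus mark such peaks but do not show why more peaks were called there. Whether raised local background explains part of the excess, or all of it, stays open. Some scores reach the ladder by chance, as 10.7% of randomly moved scores did, and lengths were highest peak ends. The other candidate, weak calls near the lowest score, remains open: the share of these sequences was 28.3% in the upper 50% by score and 56.4% in the lower, a ratio of 0.50 that sits on the bound set for it.

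The second pattern is the excess of close neighbours on the 6 arms. Splitting of 1 region into calls under 1 kb apart is argued against as the whole cause but stays open as a contributor. Merging such calls lowered the pairs from 168 (49.7 by random placement) to 78 (39.1). It lowered the ratio from 3.38 to 1.99 ± 0.23 (permutation p = 1e-04). For ratios, ± is the square root of the observed pairs over the random mean, which takes pairs as independent. Splitting of 1 region into calls with wider gaps was not tested. Dense blocks beside the centromere and uneven density over 200 kb are argued against only as the whole cause, by ratios of 2.99 without the 2 Mb beside each centromere and 2.10 with placement inside 200 kb windows (both permutation p = 1e-04). Leaving out those 2 Mb removed all of chromosome 4, whose highest peak end was 1223880, so the 2.99 covers the 5 large arms. Ladder scores were held by 38.7% of the peaks in runs and 89.0% of those alone. Raised local background at part of the clustered peaks would give this, though these sets were not matched for score. With ladder peaks alone the ratio fell from 3.38 to 1.60 ± 0.24 (43 pairs, permutation p = 0.0014). This is too close to the bound of 1.5 to decide whether raised local background is the whole cause. Off-ladder scores do not show why peaks were called close together, so whether raised local background contributes stays open as well. Of the 39 runs of 3 or more peaks on the 6 arms, 21 had no ladder score, with spans from 2.16 to 5.84 kb and a median of 4.12 kb, so copies of transposable elements may be among them, which an annotation of release 5 would show.

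The third pattern is the lower density of peaks on X, and a candidate explanation is that male embryos carry a single X, which in a collection of both sexes would lower X coverage to 0.75 of the autosomal level, a sex ratio that the labels do not give. The density of ladder peaks on X relative to 2L, 2R, 3L and 3R was 0.65 (95% interval 0.50 to 0.83), near the 0.635 expected if every autosomal pileup were multiplied by 0.75 and those under 99 reads were lost. Over all peaks it was 0.79 (0.643 to 0.963), an interval above 0.635. That expected value was computed for ladder peaks, and off-ladder peaks have no inferred k, so it does not cover all peaks. The ladder itself lowers the ratio, since 60.7% of the peaks on X had ladder scores against 69.9% to 76.2% on those 4 arms. The inferred pileup heights went the other way: the median k on X was 140 reads (95% bootstrap interval 130 to 148), against 142 on the 4 autosomal arms and 124.5 expected at that dose. Because the expected values rest on an assumed dose and on a cutoff of 99 reads, the explanation stays open.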
